A study of Mus musculus with 4 samples.

How the data were processed

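Single-cell RNA was measured in 4 libraries of mouse mammary tumor organoids, 1 library in each of 4 groups: no migration, SDF1 migration, flow migration and SDF1 migration of organoids labelled Ddr2-/-. Per the labels' protocols, live cells were sorted by flow cytometry before loading. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger on mm10, per the submitters' processing notes, which also name Partek. Per the file headers, the counts come from Cell Ranger 6.0.1 (no migration), software version 3.0.2 (flow) and Cell Ranger 4 (labelled Ddr2-/-), and the SDF1 header names no version. The no migration and Ddr2-/- labelled matrices list 32302 features, 17 of which carry no Ensembl identifier and have 0 UMIs, and the SDF1 and flow matrices list 27998. Between-library values use the 27040 Ensembl identifiers found in all 4 lists, which hold 99.4%, 99.7%, 99.8% and 99.5% of the UMIs. The deposited no migration, SDF1 and flow matrices are filtered, with 16505, 2390 and 3296 barcodes, and that of the library labelled Ddr2-/- is unfiltered, with 556888 barcodes, 227303 of them without a UMI. None of the SDF1 barcodes occurs in the no migration matrix, whereas all 2390 occur in that of the library labelled Ddr2-/-.

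Cells were barcodes with at least 1000 UMIs, 500 genes and at most 20% mitochondrial UMIs. A matrix of over 100000 barcodes also had a minimum of 10% of the 99th percentile of the UMIs of its top 3000 barcodes, which was 6830 UMIs for the library labelled Ddr2-/-. Doublet scores were computed per library after the scheme of Scrublet, as the share of simulated doublets among a cell's nearest neighbours. The top 0.8% per 1000 cells were removed as doublets, which took 1237 cells (9.95%), 45 (1.90%), 16 (1.14%) and 18 (1.18%). Each library was clustered alone, giving 17, 13, 12 and 14 clusters. The 2000 variable genes came from scanpy 1.11.5, and the 30 components and 15 neighbours from scikit-learn. Leiden clustering at resolution 0.5 was that of igraph, with modularity on a graph weighted by shared neighbours. Clusters were named "-like" after the class with the highest mean log2 CPM over its markers, out of 14 fixed marker classes, where at least 3 of these markers were detected in 10% of the cells. A cluster stayed unnamed if at least 2 of its top 10 genes by fold (prior 10 CPM, level of at least 100 CPM) were markers of another class and outnumbered its own, or if its median UMI count was under 1/3 of its library's and no marker of the name was among these genes. Many luminal clusters had no epithelial marker among their top 10 genes and rest on the mean and the detected markers. Names were rebuilt here, since the deposited data carry no cell annotation. Clusters of epithelial-like cells with more markers of other classes than of the luminal and basal classes together among their top genes were 1 SDF1 cluster (13.5% of cells, led by Col2a1, Cyp1b1, Hp and Fn1, with S100a8) and 2 clusters of the library labelled Ddr2-/- (16.4%, led by Csn1s1 and Saa1, and by Scgb1b27 and Scgb2b27). By this count there were none in the no migration and flow libraries. Within the luminal clusters, cluster 6 with flow (99 cells, Trp63) and cluster 7 of the library labelled Ddr2-/- (71 cells, Krt5) had a basal and no luminal marker among their top 10 genes and were kept as luminal. The clusters with more markers of other classes, called clusters led by markers of other classes (or other markers) below, also stayed in the class. Each had only 1 such marker among its top 10 genes, S100a8 or G0s2, and 0 of the luminal and basal classes. Against named cells outside the epithelium, however, their top 10 genes held 7, 3 and 3 epithelial markers and 0 of other classes. An alternative chosen after seeing the data left these clusters out.

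Each epithelial-like cell was thinned to 2000 UMIs, shallower cells being left out, and called positive for Krt14 or Cdh3 at 1 UMI or more. Shares carry exact Clopper-Pearson 95% intervals and CPM of summed counts exact Poisson intervals. UMIs count molecules, and both kinds of interval cover counting error only. A count of 0 is given with a floor of 3 counts. With 1 library per group no test was made between groups, and ratios carry counting intervals. For the contrasts inside libraries, raw UMIs were summed per library and class and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, robust, TMM, filterByExpr) with the library as a block, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The 4 libraries replicate the contrast although each had another treatment or genotype, so the residual holds any difference of response between them. A class needed 20 cells in a library. Krt14 and Cdh3 define the classes and were left out. Gene lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01 and with an estimated correlation, adjusted over 21 lists.

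The 21 lists, fixed from general knowledge, were basal and Krt14-linked genes, luminal secretory genes, laminin chains, other basement membrane genes, integrins and focal adhesion, cadherins, catenins and junctions, Wnt and β-catenin targets, the SDF1 and chemokine axis, hypoxia, EMT, proteases and inhibitors, collagens and their receptors, YAP and SRF targets, actin and contractility, S phase, G2/M phase, interferon response, immediate early and heat shock genes raised by cell dissociation, unfolded protein stress, genes of earlier reports on tumor leader cells, and NF-κB inflammation. Some genes stand in several lists. Between libraries, a list's median log2 ratio (prior 0.5 counts) was set against 10000 random lists matched on mean expression in 50 bins, and members at 10 CPM or more in either library were counted at a ratio step of 1.5. Genes of a contrast were named if they were among the 12 with the largest positive or negative fold past the threshold, had the same direction in every library and a mean of at least 20 CPM. Between libraries the 12 highest and 12 lowest ratios were named among genes at 50 CPM or more in either library, leaving out genes over 2 times higher in another class of at least 50 cells than in epithelial-like cells. The filters, markers, lists, tests, naming rules and all alternatives not marked as later were chosen before the data were examined. Gene positions are from GENCODE vM21 on GRCm38, the assembly that mm10 names.

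Alternatives were doublets kept, at most 10% mitochondrial UMIs, at least 3000 UMIs, resolution 1, an epithelial rule per cell (at least 2 UMIs over Epcam, Krt8, Krt18, Krt19, Krt14 and Krt5 and none of Ptprc, Pecam1, Col1a1 and Col3a1), thinning to 1000 UMIs or none, positive at 2 UMIs, sums of thinned counts, RLE scaling, no gene filter, DESeq2 1.42.0, no block, leaving out each library in turn, TMM-scaled CPM, the mean of CPM per cell, each library's own features and list genes at 10 CPM or more. Those chosen after seeing the data were thinning to 10000 UMIs, clusters led by markers of other classes left out, basal or luminal clusters alone, the unfiltered matrix from 1000 UMIs and the library labelled Ddr2-/- without barcodes shared with other libraries. The fit was tested on simulated data with 200 changed genes. Against Krt14−Cdh3− cells (12192 genes) it recovered 7.69%, 54.0% and 85.7% of genes changed 1.5-, 2- and 4-fold, with 9 false among 102 calls, and against Krt14+Cdh3− cells (12455 genes) 32.8%, 67.7% and 82.8%, with 32 false among 151 calls, when each gene kept its own dispersion. With dispersions on the trend, 2 of 101 and 7 of 128 calls were false. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9, with seed 1 throughout.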

Results

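Single-cell RNA was counted in 4 libraries of primary mammary tumor organoids from MMTV-PyMT mice, in which a viral oncogene drives breast tumors. The mice, on the FVB/n background and 10 to 12 weeks old, also carried K14-Actin.GFP, a fluorescent actin under the Krt14 promoter. Organoids of the no migration library were taken from microfluidic devices after 48 h of hypoxia without a signal. Those of the SDF1 and flow libraries were taken after 18 h of collective migration, over a mean length of 150 µm, in a gradient of the chemokine SDF1 (the product of Cxcl12) or under interstitial fluid flow. Organoids of the remaining library were labelled as lacking Ddr2, a collagen receptor, and migrated in the SDF1 gradient. Each group is 1 library, so no difference between groups has a replicate check, and hypoxia is stated for the no migration library alone. The no migration matrix held 308683883 UMIs, the SDF1 matrix 60974453, the flow matrix 33074748 and that of the library labelled Ddr2-/- 48108729. Filters left 12435, 2368, 1402 and 1519 cells, with medians of 18784, 22853, 17110 and 23269 UMIs and 3809, 4744, 3959 and 4925 genes per cell, and 11198, 2323, 1386 and 1501 cells once likely doublets were removed. Intervals below are exact 95% intervals and cover counting error only.

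Ddr2 was detected in all 4 libraries, including the library labelled Ddr2-/-. Over all cells it stood at 2.0 CPM (1.82 to 2.18, 474 UMIs) without migration, 2.35 (1.98 to 2.78, 139 UMIs) with SDF1, 1.11 (0.771 to 1.55, 34 UMIs) with flow and 1.68 (1.31 to 2.14, 68 UMIs) in the library labelled Ddr2-/-. Fibroblast-like cells stood at 54.3 CPM (49.0 to 59.9), 61.5 (51.0 to 73.5), 16.2 (10.0 to 24.8) and 12.2 (8.28 to 17.3) in the same order. Mural-like cells of the library labelled Ddr2-/- stood at 21.3 CPM (14.6 to 29.8, 33 UMIs in 58 cells), above its fibroblast-like cells (31 UMIs in 60 cells). Epithelial-like cells stood at 0.296, 0.304, 0.217 and 0.116 CPM. A Ddr2 UMI was seen in 70.2% (63.6 to 76.2), 71.6% (60.5 to 81.1), 26.2% (15.8 to 39.1) and 40.0% (27.6 to 53.5) of the fibroblast-like cells in that order, the flow library lowest, at median depths of 29552, 16804, 17883 and 34763 UMIs per cell. The gene (ENSMUSG00000026674) lies on chromosome 1 from 169972307 to 170110762 on the minus strand (mm10). The labels do not say which part was deleted, and tags from outside a deleted part would check nothing. All 68 Ddr2 UMIs in cells of the library labelled Ddr2-/- were at barcodes that no other library lists. Only 11 of its 1501 cells had a barcode that another library lists, so this does not tell where the UMIs came from.

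Epithelial-like cells made up most of every library, and basal epithelial-like cells, named from Krt14, Krt5 and other fixed markers, made up a minority. The epithelial-like share was 72.2% (71.3 to 73.0) without migration, 92.6% (91.4 to 93.6) with SDF1, 84.3% (82.3 to 86.2) with flow and 85.5% (83.7 to 87.3) in the library labelled Ddr2-/-. Basal cells were 6.92% (6.46 to 7.41), 12.7% (11.4 to 14.1), 7.72% (6.37 to 9.25) and 8.06% (6.73 to 9.56), and luminal cells 65.3%, 79.9%, 76.6% and 77.5%. The basal share was 5.21% (4.34 to 6.19) with SDF1 at resolution 1 and 16.3% (14.2 to 18.6) with flow from 3000 UMIs, so no order of the basal shares was read. Basal cells came from a single cluster in the first 3 libraries and from 2 in the library labelled Ddr2-/-. Fibroblast-like cells were 1.95%, 3.49%, 4.40% and 4.0%, and macrophage-like cells 1.55%, 1.98%, 7.0% and 4.26%. Endothelial-like cells were 0.143% without migration, 1.38% with SDF1 and 2.33% in the library labelled Ddr2-/-, and mural-like cells 3.86% in the last. From 1000 UMIs, the minimum of the other libraries, the endothelial-like share of the library labelled Ddr2-/- was 4.87% (3.94 to 5.93), and from 3000 UMIs the fibroblast-like share without migration was 0.821% (0.644 to 1.03). A flow cluster of 22 cells, with Fabp4, Esam and Rgs5 among its top genes, was named mural-like but went unnamed with doublets kept, at most 10% mitochondrial UMIs, 3000 UMIs or resolution 1, so its values are left out. Unnamed clusters of shallow cells held 24.2% of the no migration cells, at a median of 1346 UMIs, and with a minimum of 3000 UMIs per cell that library was 95.3% epithelial-like. Clusters with more top markers of other classes than of the luminal and basal classes together held 314 epithelial-like cells with SDF1 and 246 in the library labelled Ddr2-/-. Each of these clusters had only 1 such marker among its top 10 genes. Without them the epithelial-like shares were 79.0% and 69.2%.

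The series asks about a subset of tumor leader cells marked by Cdh3 (P-cadherin) among cells with Krt14, a basal keratin linked to leader cells of breast tumors. After each epithelial-like cell was thinned to 2000 UMIs, cells with both a Krt14 and a Cdh3 UMI were 0.971% (0.767 to 1.21, 77 of 7933) without migration and 2.28% (1.69 to 3.0, 49 of 2150) with SDF1. They were 4.36% (3.17 to 5.83, 43 of 986) with flow and 2.57% (1.78 to 3.59, 33 of 1284) in the library labelled Ddr2-/-. Without thinning the shares were 10.6%, 13.8%, 18.3% and 16.6%, and at 10000 UMIs per cell 5.65% (5.11 to 6.23), 8.59% (7.38 to 9.93), 15% (12.5 to 17.8) and 10.3% (8.61 to 12.2). Without thinning, however, a Krt14 UMI was seen in 73.4% of fibroblast-like and 62.1% of macrophage-like cells without migration, against 3.70% and 8.70% with SDF1, so the unthinned shares carry a background of Krt14 that differs between libraries. Thinning to 2000 UMIs left out 150 shallower cells without migration and 183 with flow. A Krt14 UMI was seen in 49.6% (48.5 to 50.7), 32.5% (30.5 to 34.5), 54.2% (51.0 to 57.3) and 40.9% (38.2 to 43.6) of epithelial-like cells. Inside basal clusters the Krt14+Cdh3+ share was 5.97% (4.41 to 7.89), 14.9% (11.1 to 19.5), 24.0% (16.0 to 33.6) and 13.2% (7.75 to 20.6), and in luminal clusters 0.433%, 0.270%, 2.14% and 1.46%. Cluster 6 with flow, with Trp63 among its top genes, held 7 of 92 cells (7.61%, 3.11 to 15.1), and cluster 7 of the library labelled Ddr2-/-, with Krt5, held 11 of 71 cells (15.5%, 8.0 to 26.0). Both stayed luminal by name, and the highest share of any other luminal cluster was 3 of 77 cells, in cluster 8 with flow. In cells that should lack Krt14, a Krt14 UMI was seen in 15 of 198 fibroblast-like cells (7.58%) and 36 of 157 macrophage-like cells (22.9%) without migration, and in 0 of 81 and 0 of 46 with SDF1. No fibroblast-like or macrophage-like cell held both genes at 2000 UMIs in any library, and for the 198 fibroblast-like cells without migration this allows up to 1.85%. Without the clusters led by markers of other classes, the share was 3.05% (2.31 to 3.94) with SDF1 and 3.37% (2.36 to 4.66) in the library labelled Ddr2-/-.

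**Figure D1:**
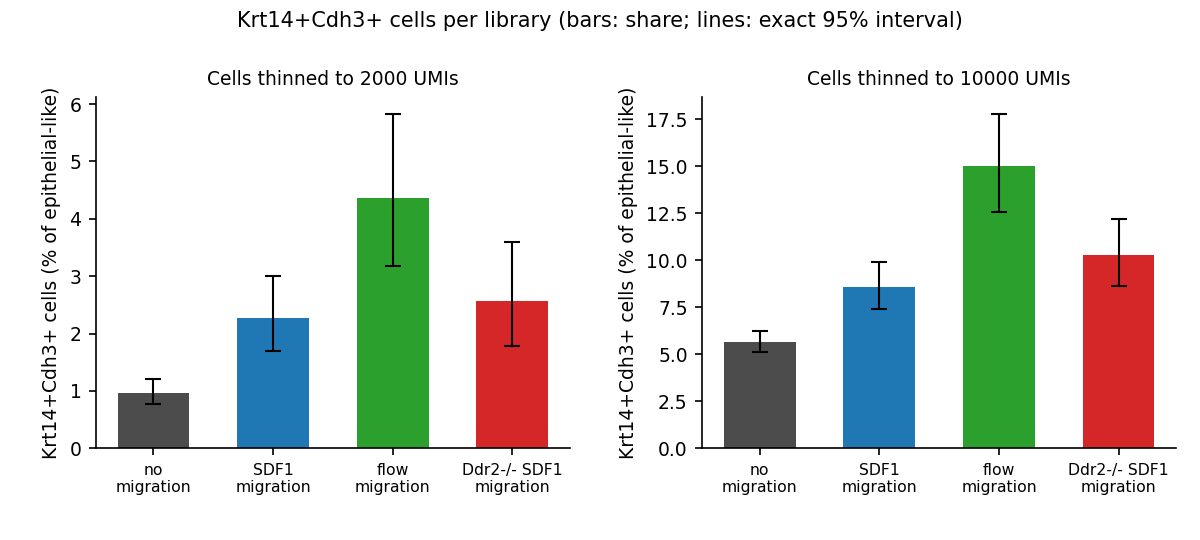
Share of epithelial-like cells (%) with at least 1 UMI of both Krt14 and Cdh3 in each of the 4 libraries, after thinning every cell to 2000 or to 10000 UMIs, with exact 95% intervals as lines. The no migration library stands at 0.971% and 5.65% and the flow library at 4.36% and 15%.

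Summed over epithelial-like cells, Cdh3 stood at 6.90 CPM without migration, 14.5 with SDF1, 21.2 with flow and 17.4 in the library labelled Ddr2-/-. The ratio was 2.11 (1.93 to 2.30) for SDF1 against no migration and 3.08 (2.79 to 3.39) for flow against no migration. It was 0.685 (0.615 to 0.763) for SDF1 against flow and 1.20 (1.07 to 1.33) for the library labelled Ddr2-/- against SDF1. Inside basal clusters Cdh3 stood at 44.7 CPM (41.8 to 47.8), 68.5 (63.3 to 74.0), 103 (91.0 to 115) and 80.6 in that order of libraries. In luminal clusters it stood at 3.25, 3.46, 12.1 and 8.09 CPM, the last 2 with cluster 6 of the flow library and cluster 7 of the library labelled Ddr2-/- included. The SDF1 to no migration ratio was 1.53 (1.38 to 1.70) inside basal clusters and 1.06 (0.890 to 1.27) inside luminal clusters. Cdh3 (ENSMUSG00000061048) lies on chromosome 8 from 106510891 to 106557297 on the plus strand, and Krt14 (ENSMUSG00000045545) on chromosome 11 from 100203162 to 100207548 on the minus strand.

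Inside each library, Krt14+Cdh3+ cells were compared with Krt14+Cdh3− cells, which asks what goes with Cdh3 among Krt14 cells. Krt5, the partner keratin of Krt14, was higher in the Krt14+Cdh3+ cells by 2.06 ± 0.06 on the log2 scale (SE, 4 libraries, adjusted p = 2.29e-13), and the laminin chain gene Lamc2 by 1.36 ± 0.08 (adjusted p = 4.4e-09). Tagln, an actin-binding protein of smooth muscle, was higher by 2.20 ± 0.08 (adjusted p = 8.77e-12), and Lalba, a milk protein gene, differed by −5.30 ± 0.26 (adjusted p = 4.46e-08). Among 12666 genes, tested on 202 Krt14+Cdh3+ and 5487 Krt14+Cdh3− cells, 790 were higher and 773 lower, of which 737 and 749 had the same direction in all 4 libraries. DESeq2 called 764 higher and 465 lower. The no migration library gave 3855 of the Krt14+Cdh3− cells. At 2000 UMIs a Krt14 UMI was also seen in 22.9% of its macrophage-like and 7.58% of its fibroblast-like cells. Some of these 3855 cells may therefore hold background Krt14 only. Without the no migration library 1058 genes passed. Of the Krt14+Cdh3+ cells 59.7%, 89.8%, 55.8% and 48.5% lay in basal clusters, in the order no migration, SDF1, flow and library labelled Ddr2-/-, and of the Krt14+Cdh3− cells 18.0%, 36.2%, 13% and 17.9%. With cells positive at 10000 UMIs, edgeR called 3656 genes over all epithelial-like cells, 691 in luminal clusters alone and 0 in basal clusters alone, where 728 had an unadjusted p under 0.05 and DESeq2 called 16. Leaving out each library in turn gave 1058 to 1283 genes, no library block 96, thinned sums 412, thinning to 1000 UMIs 800 and no thinning 4070.

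Of the genes named in the comparison with Krt14+Cdh3− cells, Myh11, Mylk and Tagln had the largest positive folds and Lalba, Klk6 and Csn1s1 the largest negative ones, each with the same direction in all 4 libraries. The smooth-muscle myosin gene Myh11 was higher by 2.95 ± 0.25, the kinase gene Mylk by 2.51 ± 0.17 and calponin, Cnn1, by 1.99 ± 0.21. The matrix protease gene Mmp2 was higher by 2.04 ± 0.14, the Wnt ligand gene Wnt10a by 1.81 ± 0.17, the matrix protein gene Postn by 1.85 ± 0.24 and the hemidesmosomal collagen gene Col17a1 by 1.80 ± 0.13. Il24, Dkk3 and Tgfbi were higher by 2.10, 1.92 and 1.80. In the other direction Klk6 differed by −3.83 ± 0.36, the casein gene Csn1s1 by −3.80 ± 0.55 and Lrg1 by −3.01 ± 0.13. Csn3, Atp6v1b1, S100a8, Cited4, Spp1, Cd14, Kit and Ankrd1 differed by −2.90 to −2.25. Adjusted p lay between 8.77e-12 and 0.0441 for these genes. Casein genes share sequence, and reads of such families may be split between them, so their values are uncertain, as are those of Krt6a and Serpina3i among near-identical copies. Inside basal clusters Krt5 differed by −0.00394, Wnt10a by −0.10, Lalba by 0.19, S100a8 by 0.25 and Ankrd1 by 0.82, against the direction over all epithelial-like cells. DESeq2 there turned Lrg1, Csn1s1 and Tgfbi too, and Il24 differed by −0.17 with an epithelial rule per cell.

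All 3 chain genes of laminin-332, the laminin of hemidesmosomes, were higher in Krt14+Cdh3+ than in Krt14+Cdh3− cells, Lama3 by 1.71 ± 0.14, Lamc2 by 1.36 ± 0.08 and Lamb3 by 1.01 ± 0.08. Krt14+Cdh3+ cells lay more often in basal clusters, so the gene and list values of this comparison include the difference between basal and luminal cells. Inside basal clusters at 10000 UMIs edgeR called 0 genes, and the fold changes had a slope of 0.178 on those over all epithelial-like cells. Lamb1 and Lamc1 were higher by 0.67 ± 0.11 and 0.42 ± 0.13. The values of Lama1 (1.57 ± 0.61, adjusted p = 0.11), Lama5 (0.36 ± 0.15), Lama4 (−0.07 ± 0.16) and Lamb2 (−0.22 ± 0.18) did not pass. Of 9 laminin genes, 5 were higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone (adjusted p = 3.01e-11 as a list, and adjusted p = 0.0398 with an estimated correlation). Of 31 integrin and focal adhesion genes, 24 were higher and 1 lower, and 25 and 2 adjusted over the list alone (adjusted p = 1.24e-18, and adjusted p = 0.0398 with an estimated correlation). Among them Tns1 was higher by 1.70 ± 0.27, Itga2 by 1.22 ± 0.12, Itgb4 by 0.80 ± 0.09 and Itga6 by 0.78 ± 0.07, and Tln2 differed by −0.94 ± 0.19. Of 18 basal genes, 15 were higher and 0 lower, and 18 and 0 adjusted over the list alone (adjusted p = 2.97e-68, and adjusted p = 0.0184 with an estimated correlation). Trp63 was higher by 1.31 ± 0.11 and Krt17 by 1.26 ± 0.07. The basal list holds the markers that named the basal clusters, so its rise is not separate from the larger basal share. Acta2 (1.93 ± 0.33), Igfbp2 (1.87 ± 0.47) and Lgals7 (0.95 ± 0.28) did not pass over all genes. Of 21 cadherin, catenin and junction genes, 9 were higher and 0 lower, and 10 and 1 adjusted over the list alone (adjusted p = 1.47e-05, and adjusted p = 0.056 with an estimated correlation). Nectin1 was higher by 1.08 ± 0.12, Dsp by 0.97 ± 0.08, Cdh2 by 0.90 ± 0.20 and Cdh1, E-cadherin, by 0.30 ± 0.08. The β-catenin gene Ctnnb1 differed by −0.00 ± 0.07 (adjusted p = 0.99). The 19 Wnt and β-catenin target genes gave 1 higher and 2 lower, with Porcn at 0.94 ± 0.19 and Nkd2 at −1.97 ± 0.16 (adjusted p = 0.753 with an estimated correlation). Their median lay above 0 and their mean below it.

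**Figure D2:**
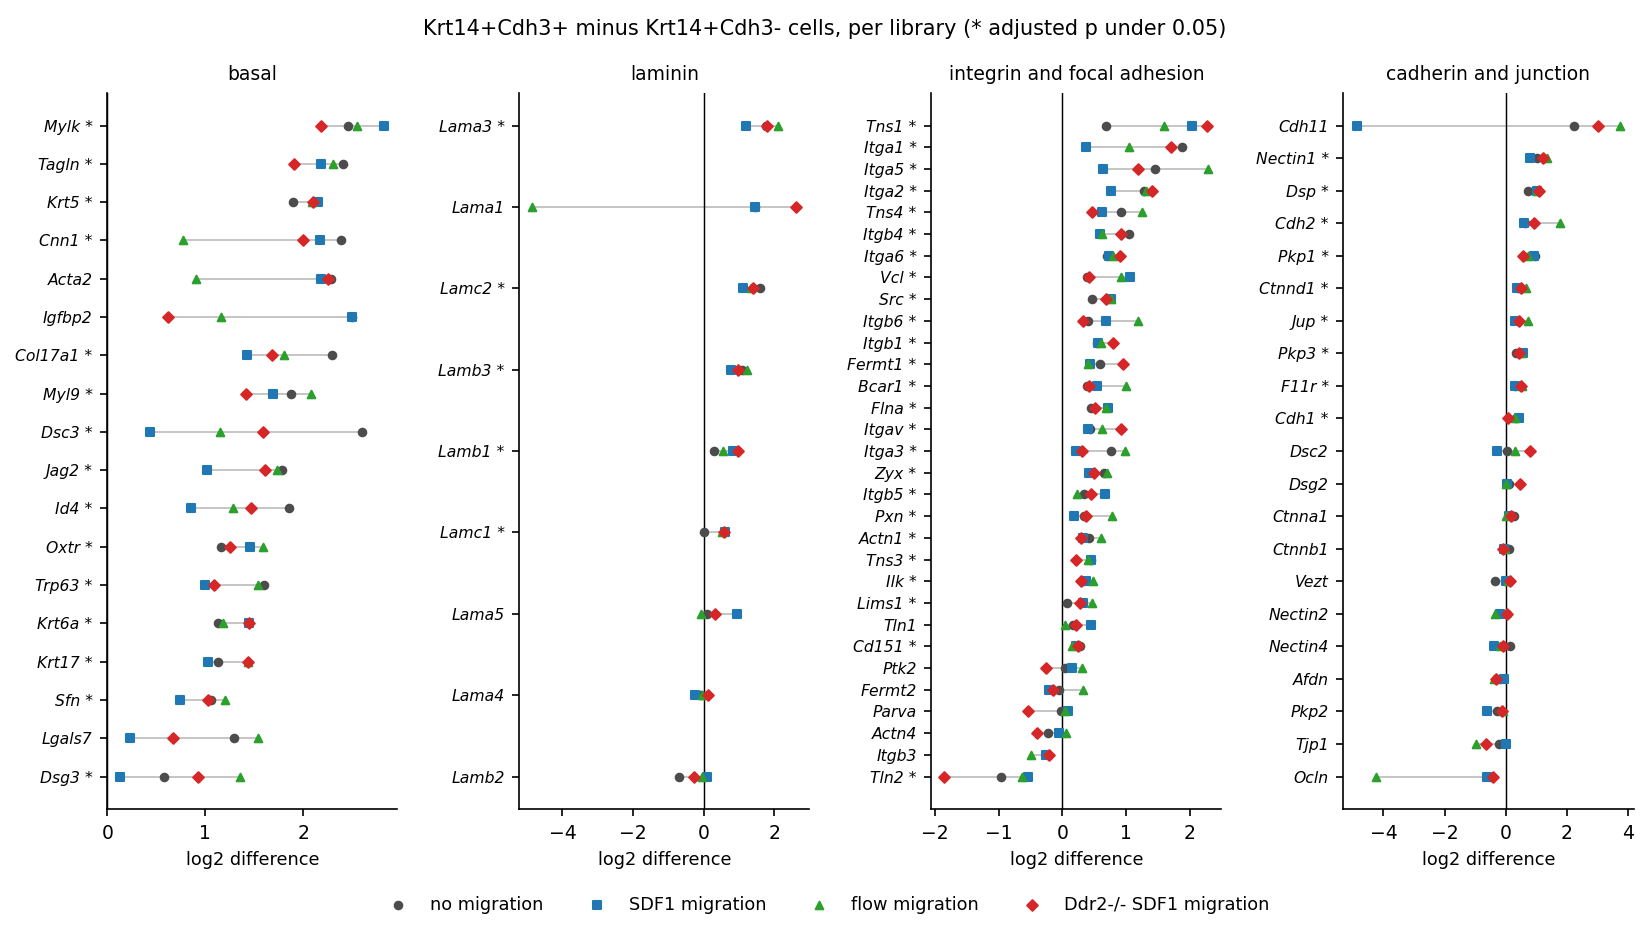
Log2 difference of Krt14+Cdh3+ minus Krt14+Cdh3− epithelial-like cells (x axis) for each gene of the basal, laminin, integrin and cadherin lists, with a point per library and a star at adjusted p under 0.05. Lama3, Lamb3 and Lamc2 lie above 0 in all 4 libraries, and the spread of Lama1, Cdh11 and Ocln rests on few counts.

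The remaining lists of the Krt14+Cdh3+ against Krt14+Cdh3− comparison passed with the preset correlation or not at all. Of 22 luminal secretory genes, 0 were higher and 12 lower, and 0 and 17 adjusted over the list alone (adjusted p = 1.33e-24, and adjusted p = 0.056 with an estimated correlation). Lcn2 stood at −1.71 ± 0.24. Of 11 other basement membrane genes, 7 were higher and 1 lower, and 8 and 1 adjusted over the list alone (adjusted p = 4.42e-11, and adjusted p = 0.093 with an estimated correlation). Col4a2 stood at 1.39 ± 0.15, Col7a1 at 1.28 ± 0.10 and Npnt at −1.88 ± 0.27. Genes named in earlier reports on tumor leader cells gave 8 higher and 1 lower of 14, and 11 and 1 adjusted over the list alone (adjusted p = 2.76e-18, and adjusted p = 0.056 with an estimated correlation). The 21 EMT genes gave 6 and 0, the 26 protease genes 6 and 1 and the 17 collagen genes 5 and 1 (adjusted p = 0.0944, 0.188 and 0.425 with an estimated correlation). Snai2 stood at 1.27 ± 0.10, Serpine2 at −0.59 ± 0.09 and Loxl2 at 1.67 ± 0.22. The 23 YAP target genes gave 7 and 1 and the 41 actin genes 16 and 1, with Axl at 1.38 ± 0.15, Tpm2 at 0.89 ± 0.10 and Ezr at −0.49 ± 0.09 (adjusted p = 0.0751 and 0.188 with an estimated correlation). The 39 hypoxia genes gave 7 and 0, among them Slc2a1 at 1.00 ± 0.19 and Vegfa at 0.77 ± 0.10 (adjusted p = 0.425 with an estimated correlation). The 25 S phase genes gave 0 and 0, the 26 G2/M genes 0 and 1 and the 23 interferon genes 0 and 1, with Rsad2 at −1.53 ± 0.26 (adjusted p = 0.451, 0.425 and 0.387 with an estimated correlation). The S phase list passed with the preset correlation at 0.0381, the G2/M list at 4.5e-05 and the interferon list at 0.0348. All 3 of these lists had the other direction under some settings. The 12 SDF1 axis genes gave 1 and 1, with Cxcl12 at 1.22 ± 0.21 and Ccl20 at −2.53 ± 0.34. The 22 immediate early genes gave 4 and 2, the 19 unfolded protein genes 0 and 4 with Xbp1 at −1.20 ± 0.12, and the 22 NF-κB genes 1 and 2 with Icam1 at 1.12 ± 0.18. These 4 lists had adjusted p = 0.876, 0.722, 0.386 and 0.425 with an estimated correlation.

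Krt14+Cdh3+ cells were also compared with Krt14−Cdh3− cells, which asks what marks them among all tumor epithelium. Of the Krt14−Cdh3− cells only 0.703%, 1.10%, 2.03% and 2.24% lay in basal clusters, against 59.7%, 89.8%, 55.8% and 48.5% of the Krt14+Cdh3+ cells, so the values of this comparison include the difference between basal and luminal cells. Krt5 was higher by 8.46 ± 0.97 on the log2 scale (SE, 4 libraries, adjusted p = 0.0158), Col17a1 by 6.77 ± 0.35 (adjusted p = 0.000209) and Tagln by 5.33 ± 0.18 (adjusted p = 2.8e-07). The casein gene Csn1s2a had 5260 UMIs in Krt14−Cdh3− and 0 in Krt14+Cdh3+ cells, at least 56.2-fold lower against a floor of 3 counts over the group. Among 12507 genes, tested on 202 and 6634 cells, 1261 were higher and 1481 lower, of which 1198 and 1448 had the same direction in all 4 libraries. Without the SDF1 library 1544 genes passed and without the library labelled Ddr2-/- 1613, against 2742 with all 4. Thinned sums gave 945 genes, no library block 1099, thinning to 10000 UMIs 3422 and no thinning 2653, so which of the 2 comparisons had more genes depended on the depth. Tgfbi, Stmn2, Acta2, Serpina3i, Fst, Snai2, Dkk3, Cntfr and Krt6a were higher by 4.72 to 7.07. Lalba, Csn1s1, Lrg1, Csn3, Npy, Fcgbp, Car6, Atp6v1b1, Bglap3 and Foxi1 differed by −7.80 to −4.15, and Scgb2b27, with 2 UMIs in Krt14+Cdh3+ cells, by −8.09 ± 0.48. No list passed in this comparison with an estimated correlation.

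Laminin-332 genes were also higher in Krt14+Cdh3+ than in Krt14−Cdh3− cells, Lama3 by 4.48 ± 0.38 (adjusted p = 0.0024), Lamc2 by 3.26 ± 0.25 (adjusted p = 0.00038) and Lamb3 by 1.82 ± 0.12 (adjusted p = 8.3e-06). Lamb1 and Lamc1 were higher by 1.61 ± 0.37 and 0.60 ± 0.19, and Lamb2 differed by −0.82 ± 0.17. Of 9 laminin genes, 5 were higher and 1 lower, both over all genes and adjusted over the list alone (adjusted p = 2.7e-06, and adjusted p = 0.16 with an estimated correlation). Of 18 basal genes, 16 were higher and 0 lower, and 17 and 0 adjusted over the list alone (adjusted p = 1.82e-44, and adjusted p = 0.0636 with an estimated correlation). Trp63 was higher by 4.08 ± 0.17. Of 31 integrin genes, 24 were higher and 1 lower, and 25 and 2 adjusted over the list alone (adjusted p = 4.73e-18, and adjusted p = 0.209 with an estimated correlation). Itga5 stood at 3.16 ± 0.24, Itgb4 at 1.57 ± 0.15, Itga6 at 0.99 ± 0.11 and Fermt2 at −0.44 ± 0.12. Of 21 cadherin and junction genes, 10 were higher and 1 lower, and 12 and 5 adjusted over the list alone (adjusted p = 0.000375, and adjusted p = 0.328 with an estimated correlation). Pkp1 stood at 2.74 ± 0.45, Dsp at 2.46 ± 0.36, Cdh2 at 2.32 ± 0.32, Cdh1 at 0.48 ± 0.12 and Ocln at −1.61 ± 0.39. Ctnnb1 stood at 0.19 ± 0.11 (adjusted p = 0.25). Lama3 (ENSMUSG00000024421) lies on chromosome 18 from 12333819 to 12583013 and Lamb3 (ENSMUSG00000026639) on chromosome 1 from 193207699 to 193343878, both on the plus strand. Lamc2 (ENSMUSG00000026479) lies on chromosome 1 from 153122756 to 153186447 on the minus strand.

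The other lists of the comparison with Krt14−Cdh3− cells follow, with counts of genes higher and lower. The 22 luminal secretory genes gave 0 higher and 11 lower, and 1 and 18 adjusted over the list alone (adjusted p = 1.26e-10, and adjusted p = 0.223 with an estimated correlation). The 14 leader report genes gave 11 and 2 (adjusted p = 2.85e-17, and adjusted p = 0.0789 with an estimated correlation). The 11 other basement membrane genes gave 6 and 1, the 20 EMT genes 9 and 0, the 25 protease genes 13 and 1 and the 18 collagen genes 5 and 1 (adjusted p = 0.223, 0.112, 0.149 and 0.223 with an estimated correlation). Col7a1 stood at 4.28 ± 0.46, Postn at 4.57 ± 0.13, Plau at 3.32 ± 0.34 and Mmp3 at −1.53 ± 0.34. The 23 YAP target genes gave 10 and 2 and the 41 actin genes 21 and 2, with Axl at 3.14 ± 0.17, Birc5 at −1.59 ± 0.27 and Tpm2 at 2.41 ± 0.34 (adjusted p = 0.303 and 0.328 with an estimated correlation). The 17 Wnt and β-catenin target genes gave 3 and 3, among them Porcn at 2.94 ± 0.19 and Rnf43 at −1.09 ± 0.27, and the 12 SDF1 axis genes 2 and 0, Cxcl16 at 1.14 ± 0.15 and Cxcl12 at 0.98 ± 0.20 (adjusted p = 0.421 and 0.533 with an estimated correlation). The 38 hypoxia genes gave 6 and 5, with Slc16a3 at 1.72 ± 0.19 and Ero1l at −1.27 ± 0.15. Their median lay below 0 and their mean above it. The 25 S phase genes gave 1 and 0, the 26 G2/M genes 0 and 1, and the 23 interferon genes 0 and 6 with Ifit3 at −2.26 ± 0.39. These 4 lists had adjusted p = 0.983, 0.983, 0.713 and 0.462 with an estimated correlation. The 22 immediate early genes gave 1 and 5 with Jund at −0.92 ± 0.15, the 19 unfolded protein genes 0 and 5 with Xbp1 at −2.18 ± 0.35, and the 22 NF-κB genes 5 and 1 with Icam1 at 2.94 ± 0.53 (adjusted p = 0.624, 0.223 and 0.421 with an estimated correlation). The G2/M and NF-κB lists had the other direction under some settings.

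Epithelial-like cells of the SDF1 library were set against those of the no migration library, which asks what goes with migration towards the chemokine. Laminin-332 genes stood close to each other in both, with Lama3 at 46.9 against 42.1 CPM, a ratio of 1.11 (1.07 to 1.16), Lamc2 at a ratio of 0.969 (0.943 to 0.997) and Lamb3 at 0.846. These ratios pool basal and luminal clusters, whose shares differed between the libraries. Inside basal clusters Lamc2 stood lower with SDF1 than without migration. Hypoxia genes stood lower with SDF1, Vegfa at 66.0 against 302 CPM and Hk2 at 12.7 against 100 CPM. The no migration organoids were taken after 48 h of hypoxia and the SDF1 organoids after 18 h of migration. Hypoxia, time and migration are therefore not told apart here. Clusters with Ero1l, Adm or Bnip3 among their top genes held 1659 of 8083 epithelial-like cells without migration (cluster 3) and 164 and 110 of 2150 with SDF1 (clusters 5 and 7). Ratios of the whole class do not separate a change inside cells from another mix of clusters. The phosphatase gene Ptp4a1 had the highest ratio of the named genes, 141 (126 to 158), from 200 against 1.42 CPM. Wap, a whey protein gene, followed at 61.6 (53.5 to 71.2), and Tonsl, Nutf2, Ahcy, Csn1s2a, Csn2, Scgb2b27, Srp54c, Ltf, Nme3 and Coro1b had ratios of 54.5 to 20.1. Spink12 had 1 UMI with SDF1 against 81.8 CPM without migration, a 4554-fold difference with an interval from 817 to 179872. Spink12, Asprv1, Klk14 and Klk6 were among the top genes of no migration cluster 13, with 103 of the 8083 epithelial-like cells. No SDF1 cluster had them among its top genes. Tsix, antisense to Xist, was 49.2-fold lower (39.7 to 61.6), Cx3cr1 40.0-fold (35.4 to 45.5) and Spata7 39.8-fold (36.2 to 44.0). The values of Ptp4a1, Tonsl, Tomm6 and Tsix are uncertain, since each overlaps on its own strand a gene that only 1 kind of feature list holds. Klk14, Egr3, Fam89b, Asprv1, Cstdc5, Gdpd3, Klk6 and Tomm6 were 32.0- to 7.13-fold lower. Of these 24 genes, 16 set the no migration library apart from all 3 others by over 2-fold. Along the 2 feature lists of the matrices 8 split by over 2-fold, Fam89b, Tomm6 and Tonsl, and also Egr3, Ptp4a1, Spink12, Srp54c and Tsix, which are among the 16. The no migration library shares its list with the library labelled Ddr2-/-. In neither group were 5 genes, Wap, Csn1s2a, Csn2, Scgb2b27 and Cstdc5.

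The luminal secretory and immediate early lists stood at percentile 100 and the hypoxia list at percentile 0 in the SDF1 to no migration comparison. Counts here are of genes at 10 CPM or more in either library that were 1.5-fold higher or lower, and medians are log2 ratios. Percentiles are among 10000 random lists matched on expression, as a description of these libraries. The median gene over 10 CPM stood at 0.25 for SDF1 and 0.28 for flow against no migration, −0.05 for SDF1 against flow and 0.07 for the library labelled Ddr2-/- against SDF1. TMM scaling moved log2 ratios by −0.31, −0.36, 0.05 and −0.07. The immediate early list, with heat shock genes such as Hspa1a and Dnajb1, was set up as a sign of cell dissociation, so handling of the cells is not separated from migration in these values. Of its 22 genes, 14 were higher and 1 lower (median 1.03, percentile 100), with Zfp36 at a ratio of 7.61 (7.52 to 7.69) and Jund at 4.0 (3.95 to 4.05). Of 22 luminal secretory genes, 12 were higher and 2 lower (median 1.13, percentile 100), with Krt19 at 0.452, but inside basal clusters the percentile was 80.6. Of 37 hypoxia genes, 1 was higher and 25 lower (median −0.88, percentile 0), with Hk2 at 0.126 (0.117 to 0.136), Pgk1 at 0.338 and Ddit4 at 1.71. Hypoxia, of 48 h, is stated for the no migration library alone, so this list does not separate it from migration. Of 20 interferon genes, 1 was higher and 8 lower (median −0.26, percentile 0.28), with Ifi44 at 0.226 (0.211 to 0.243) and Bst2 at 0.323, but for the mean of CPM per cell the percentile was 4.16. Lists at low percentiles that moved inside the central 95% of random lists for basal clusters alone were the Wnt targets (4 and 3 of 12, −0.28, 0.99), the other basement membrane genes (2 and 1 of 10, −0.29, 0.98), the SDF1 axis (1 and 6 of 10, −0.21, 1.43) and the G2/M genes (2 and 5 of 16, −0.02, 1.51). Porcn had a ratio of 4.88 (4.56 to 5.23), Lgr4 of 0.358, Cxcl12 of 2.0 (1.81 to 2.21), Ccl20 of 0.206 (0.190 to 0.223) and Prc1 of 0.386.

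The basal list stood at percentile 92.9 for SDF1 against no migration, with 7 of 15 genes higher and 1 lower (median 0.52). Trp63 stood at a ratio of 2.23 (2.12 to 2.34), Krt14 at 1.41 (1.40 to 1.42) and Krt5 at 1.31. These ratios pool basal and luminal clusters, and the basal share differed between these libraries as the clusters were named. A change inside basal cells is therefore not shown by them. Without the clusters led by markers of other classes that percentile was 99. The 8 laminin genes gave 1 higher, Lamb2 at 1.92 (1.81 to 2.04), and 0 lower (median −0.02, percentile 14.2). The 28 integrin genes gave 5 and 3 (0.27, 75.0), with Cd151 at 2.30 (2.25 to 2.35), Itgb1 at 0.585 (0.576 to 0.595) and Itga2 at 0.173 (0.158 to 0.189). The 20 cadherin and junction genes gave 4 and 3 (0.02, 11.5), with Cdh1 at 1.01 (0.983 to 1.04), Ctnnb1 at 1.00 and Cdh2 at 0.486. EMT gave 7 and 2 of 17 (0.19, 42.2), proteases 7 and 3 of 21 (0.08, 17.1), collagens 4 and 3 of 9 (0.75, 96.2), YAP targets 5 and 4 of 23 (0.13, 34.1) and actin genes 7 and 8 of 40 (−0.00, 23.9). Examples were Mmp2 at 5.95 (5.35 to 6.63), Loxl2 at 0.139, Klf2 at 6.59, S100a4 at 0.0817 and Ddr1, another collagen receptor gene, at 2.36 (2.28 to 2.45). S phase genes gave 5 and 0 of 16 (0.34, 51.0), unfolded protein genes 5 and 2 of 18 (−0.03, 12.2), leader report genes 4 and 0 of 14 (0.16, 41.9) and NF-κB genes 5 and 7 of 20 (0.34, 79.2). Rrm2 stood at 1.93, Xbp1 at 3.78 (3.73 to 3.83) and Saa2 at 3.02.

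Flow was set against no migration to ask what goes with migration under a mechanical signal. Ctnnb1 stood at 332 against 200 CPM, a ratio of 1.66 (1.62 to 1.70), Lamc1 at 1.51 (1.42 to 1.61) and Lama3 at 1.32 (1.25 to 1.39). Lamc2 stood at 1.05 (1.02 to 1.09) and Lamb3 at 0.955. These ratios pool basal and luminal clusters. Ptp4a1 again had the highest ratio of the named genes, 168 (150 to 189), and the transcription factor gene Cebpb stood at 1245 against 107 CPM, a ratio of 11.6 (11.4 to 11.8). Tonsl, Nutf2, Ahcy, Srp54c and Hmga1 had ratios of 51.6 to 28, and Chtf8, Nme3, Taf6l, Gstp1 and Dapk3 of 16.7 to 10.0. Spink12 had 0 UMIs with flow and was at least 754-fold lower against a floor of 3 counts in the library. Spink12, Klk14 and Asprv1 were among the top genes of no migration cluster 13 (103 cells) and of no flow cluster. Klk14 was 49.4-fold lower (34.2 to 74.4), Cx3cr1 46.4-fold (38.4 to 56.6) and Egr3 36.3-fold (29.8 to 44.8). Tsix, Spata7, Fam89b, Gdpd3, Asprv1, Wdr89, Mia and Btbd7 were 31.5- to 5.31-fold lower. Of these 24 genes, 19 set the no migration library apart from all 3 others by over 2-fold and 8 split along the feature lists, leaving Wdr89 and Mia in neither group. The values of Ptp4a1, Tonsl, Chtf8 and Tsix are uncertain, since each overlaps a gene that only 1 kind of feature list holds.

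The interferon list stood highest for flow against no migration, with 11 of 21 genes higher and 1 lower (median 0.71, percentile 99.6), Ifit3 at a ratio of 6.31 (5.71 to 6.97) and Rsad2 at 4.66 (4.42 to 4.90). A flow cluster of 75 cells had Rsad2, Ifit3 and Mx1 among its top genes, and no cluster without migration did. The integrin genes gave 10 and 1 of 28 (0.52, 98.1, and percentile 96.8 with doublets kept), with Cd151 at 2.81 (2.73 to 2.88), Zyx at 2.46 (2.40 to 2.53) and Itga2 at 0.300 (0.272 to 0.331). S phase genes gave 13 and 0 of 21 (0.67, 97.8, and 96.6 with at most 10% mitochondrial UMIs) and G2/M genes 13 and 0 of 21 (0.64, 97.1), with Rrm2 at 2.82 (2.56 to 3.10) and Plk1 at 2.70 (2.39 to 3.04). Hypoxia genes gave 6 and 9 of 37 (−0.09, 0.945), with Hk2 at 0.358 (0.336 to 0.382), Vegfa at 0.543 (0.527 to 0.560) and Ddit4 at 2.58 (2.54 to 2.61). Their percentile was 23.1 for the mean of CPM per cell. Here too the no migration library was taken after 48 h of hypoxia, so hypoxia is not separated from migration. Basal genes gave 6 and 1 of 15 (0.35, 69.6), with Trp63 at 3.02 (2.85 to 3.19) and Krt5 at 2.33 (2.28 to 2.38). These ratios pool basal and luminal clusters, so a change inside basal cells is not shown by them. Flow cluster 6, named luminal, had Trp63 among its top genes. Laminin genes gave 2 and 0 of 8 (0.40, 61.6) and cadherin and junction genes 8 and 3 of 21 (0.42, 83.1), with F11r at 2.23 (2.17 to 2.28), Cdh1 at 0.988 and Cdh2 at 0.461. Other basement membrane genes gave 1 and 0 of 10 (−0.12, 3.73), Wnt targets 3 and 2 of 11 (0.14, 17.6) and the SDF1 axis 2 and 4 of 9 (0.05, 8.17). Myc stood at 3.32 (3.18 to 3.47), Ccl5 at 2.90 and Ccl20 at 0.227. Proteases gave 12 and 1 of 23 (0.46, 90.5, and 100 for basal clusters alone), with Mmp3 at 7.69 (7.25 to 8.15) and Mmp9 at 0.240. Luminal secretory genes gave 5 and 6 of 21 (0.31, 86.5), with Cldn4 at 4.84 (4.76 to 4.91) and Trf at 0.311. Actin genes gave 16 and 6 of 40 (0.37, 96.6) with Actg1 at 3.35, YAP targets 8 and 2 of 23 (0.28, 58.3) and immediate early genes 9 and 4 of 22 (0.39, 95.7) with Zfp36 at 3.30. EMT gave 6 and 1 (0.20, 36.9), collagens 1 and 1 (0.38, 62.1), unfolded protein genes 4 and 2 (0.11, 23.4), leader report genes 5 and 1 (0.27, 58.2) and NF-κB genes 7 and 3 (0.31, 65.5).

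SDF1 was set against flow to ask how the chemical and the mechanical signal differ. Ctnnb1 stood at 200 CPM with SDF1 and 332 with flow, a ratio of 0.602 (0.585 to 0.619), Krt5 at 0.560 (0.547 to 0.574), Lamc1 at 0.649 (0.60 to 0.703) and Lama3 at 0.845 (0.793 to 0.901). These ratios pool basal and luminal clusters, so a change inside basal cells is not shown by them. Csn2 had the highest ratio of the named genes. It stood at 449 CPM with SDF1 and had 0 UMIs with flow, at least 4138-fold higher against a floor of 3 counts in the library. An SDF1 cluster of 574 cells had Csn2, Csn1s2a, Csn1s1 and Wap among its top genes, and no flow cluster did, so these ratios go with cells in different clusters. Csn1s2a stood at 95.5 (64.1 to 149), Scgb2b27 at 53.4 (43.2 to 66.8), Wap at 38.1 (28.1 to 53.0), Csn1s1 at 24.8 (22.3 to 27.6) and Lalba at 23.1 (21.8 to 24.6). Npy, Fcgbp, Ecrg4, Car6, H2-Q2 and Muc15 had ratios of 17.0 to 9.95. In the other direction Cstdc5 was 7.63-fold lower, the hypoxia genes Ero1l and Adm 4.14-fold (4.03 to 4.26) and 3.76-fold (3.61 to 3.91). Gbp2, Foxj1, Csf3, Car13, Bsg, Hmga1, Plk2, Espn and Mt2 were 3.86- to 2.5-fold lower. Of these 24 genes, Hmga1 alone set the no migration library apart by over 2-fold and 0 split along the feature lists.

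Hypoxia, cycle and interferon lists stood at percentile 0 for SDF1 against flow. Hypoxia genes gave 1 higher and 28 lower of 37 (median −0.78), with Vegfa at a ratio of 0.403 (0.385 to 0.421). Clusters with Ero1l, Adm or Bnip3 among their top genes held 164 and 110 of 2150 epithelial-like cells with SDF1 and 274 of 1169 with flow. The hypoxia ratios therefore do not separate a change inside cells from another mix of clusters. G2/M genes gave 0 and 16 of 21 (−0.72), with Anln at 0.328 (0.293 to 0.366) and Prc1 at 0.460. S phase genes gave 0 and 7 of 21 (−0.42) and interferon genes 0 and 16 of 21 (−0.93), with Rsad2 at 0.143 (0.131 to 0.156) and Usp18 at 0.263. Actin genes also stood at percentile 0, with 0 and 4 of 39 (−0.33) and Actg1 at 0.609. Integrin genes gave 1 and 4 of 28 (−0.22, percentile 1.83), with Itga2 at 0.576 and Itga3 at 0.581 (0.555 to 0.608). Proteases gave 2 and 8 of 22 (−0.22, 1.34), with Mmp3 at 0.0694 and Plaur at 0.323 (percentile 7.17 for genes at 10 CPM or more), and YAP targets 1 and 4 of 23 (−0.28, 0.4), with Ccn2 at 0.507. The percentile of the YAP targets was 79.4 inside basal clusters. Luminal secretory genes gave 11 and 4 of 22 (0.57, 100), with Krt18 at 0.480 (0.477 to 0.484). Immediate early genes gave 12 and 1 of 21 (0.66, 100, and 68.8 inside basal clusters), with Fos at 2.53 (2.5 to 2.56) and Btg2 at 2.44. Basal genes gave 3 and 2 of 14 (0.22, 99.8) and collagens 2 and 2 of 8 (0.37, 99.7), but inside basal clusters these percentiles were 0.02 and 0.11, and for collagens 23.4 as the mean per cell and 0 with the rule per cell. Laminin genes gave 0 and 1 of 8 (−0.24, 10.9) and cadherin and junction genes 0 and 1 of 20 (−0.19, 7.83), with Cdh1 at 1.02. Other basement membrane genes gave 1 and 2 (−0.14, 22.5) with Npnt at 3.39 and Col4a1 at 0.479, and Wnt targets 2 and 1 (0.01, 72.0) with Myc at 0.485. The SDF1 axis gave 1 and 3 of 10 (−0.14, 31.8) with Cxcl12 at 1.78 (1.5 to 2.13) and Ccl5 at 0.156. EMT gave 0 and 1 (−0.16, 15), and unfolded protein genes 2 and 0 of 18 (−0.20, 5.95) with Herpud1 at 2.06. Leader report genes gave 1 and 1 (−0.15, 18.7) with Notch1 at 1.66, and NF-κB genes 1 and 4 (−0.14, 15.9) with Tnf at 1.62 and Csf3 at 0.347. Laminin, other basement membrane, EMT and leader report genes stood at percentiles of 0.59, 0.23, 0.02 and 0.03 inside basal clusters.

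**Figure D3:**
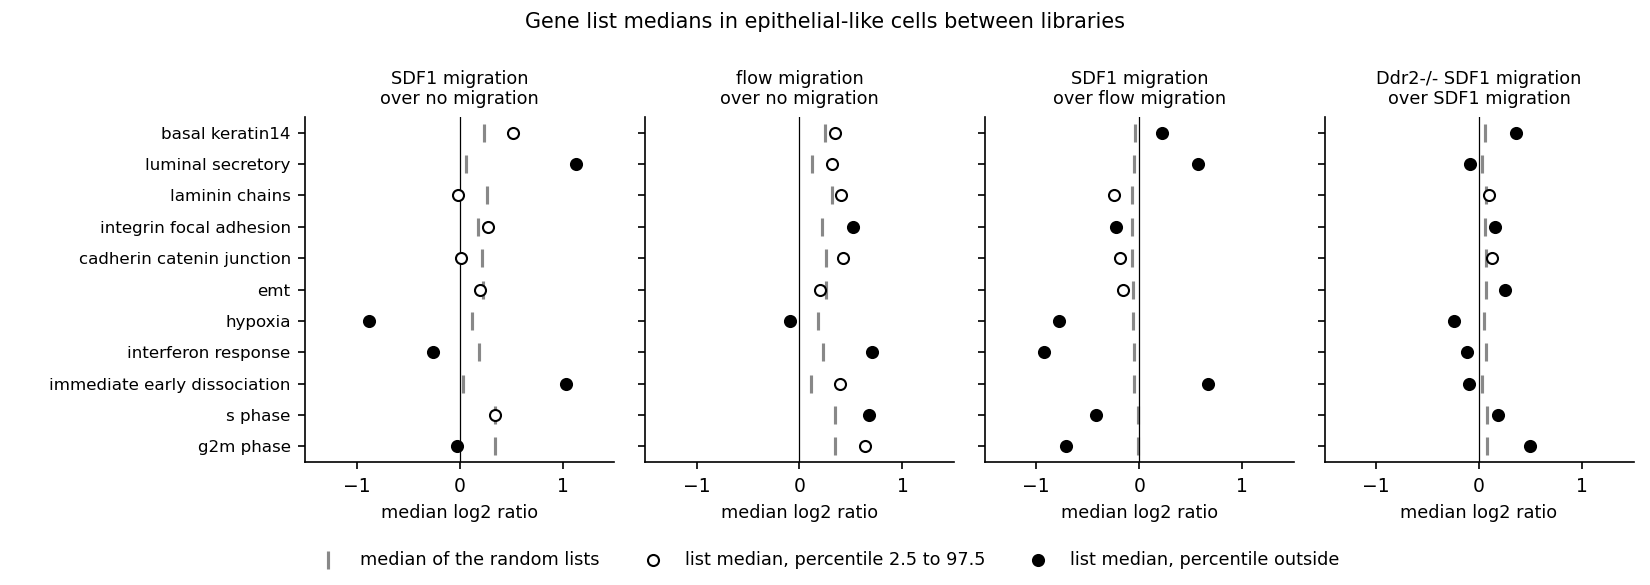
Median log2 ratio of each gene list (x axis) in the 4 comparisons of epithelial-like CPM, with the median of random lists as a grey tick and filled points where the percentile lies outside the central 95%. The hypoxia list lies at −0.88 for SDF1 against no migration and −0.78 for SDF1 against flow.

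The library labelled Ddr2-/- was set against the SDF1 library to ask what goes with loss of this collagen receptor during migration towards SDF1, with the direction resting on a label that Ddr2 itself could not check. Lama3 stood at 39.9 against 46.9 CPM, a ratio of 0.852 (0.798 to 0.910), Lamc2 at 0.807 (0.773 to 0.843), Lamb3 at 0.999 and Ctnnb1 at 1.15. These ratios pool basal and luminal clusters, and the basal share with SDF1 depended on the resolution of the clusters. A fall of laminin genes inside basal cells is therefore not shown by them. Inside basal clusters Lamc2 stood only a little lower in the library labelled Ddr2-/- than with SDF1. Trf, transferrin, stood at 4736 against 916 CPM, a ratio of 5.17 (5.12 to 5.22), and the YAP target gene Ankrd1 at 2.43 (2.30 to 2.57). Fam89b had the highest ratio of the named genes, 29.6 (25.6 to 34.3), and Tomm6, Klk10, Rnasek, Dpm1, Nme1, Sys1, Foxj1, Srek1 and Ndst1 had ratios of 12.2 to 2.30. Ptp4a1 was 54.8-fold lower (46.0 to 65.9), Tonsl 34.6-fold and Csn2 13.4-fold (12.6 to 14.2). Taf6l, Srp54c, H2-Q2, Csn1s2a, Wdr89, Gclm, Sap18b, Nxf1 and Eno1b were 9.69- to 3.23-fold lower. Of these 24 genes, 13 split the libraries by over 2-fold along the feature lists, and 9 (Sys1, Ankrd1, Foxj1, Srek1, Csn2, H2-Q2, Csn1s2a, Wdr89 and Eno1b) neither did so nor set the no migration library apart. The values of Ptp4a1, Tonsl, Tomm6 and Dpm1 are uncertain, since each overlaps a gene that only 1 kind of feature list holds.

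Basal, G2/M and EMT lists stood at percentiles above 99.9 for the library labelled Ddr2-/- against SDF1, with small medians. Basal genes gave 6 higher and 0 lower of 18 (median 0.36, percentile 100), with Igfbp2 at a ratio of 2.58 (2.39 to 2.79) and Id4 at 2.42 (2.05 to 2.87), and Krt14 at 1.12. G2/M genes gave 5 and 0 of 20 (0.50, 100), with Plk1 at 1.75 (1.53 to 2.01) and Nusap1 at 1.69, and EMT genes 3 and 0 of 17 (0.25, 99.99), with Vim at 1.71 (1.66 to 1.76) and S100a4 at 2.82. Wnt targets gave 2 and 0 of 12 (0.41, 100, but 75.6 for genes at 10 CPM or more), with Nkd2 at 1.88 (1.78 to 1.97). Actin genes gave 1 and 0 of 39 (0.15, 99.99), integrin genes 1 and 0 of 28 (0.16, 99.8) with Itga2 at 1.80 (1.59 to 2.04), and proteases 2 and 0 of 19 (0.16, 99.2) with Serpine2 at 1.96 and Timp3 at 1.72. S phase genes gave 0 and 0 of 19 (0.18, 99, but 76.7 inside basal clusters), and YAP targets 3 and 0 of 23 (0.14, 97.8, but 88.3 inside basal clusters). Hypoxia genes gave 0 and 4 of 37 (−0.24, 0, but 96.1 inside basal clusters), with Selenbp1 at 0.518 (0.476 to 0.563) and Ero1l at 0.559 (0.534 to 0.584). Interferon genes gave 0 and 1 of 20 (−0.12, 0.01) with Irf7 at 0.658 and immediate early genes 0 and 1 of 22 (−0.10, 0.22) with Hspa1a at 0.506. Luminal secretory genes gave 1 and 4 of 22 (−0.09, 0.32, and 2.74 with at most 10% mitochondrial UMIs). Collagens gave 0 and 2 (−0.10, 0.72), a side that did not hold, since their percentile was 98.0 inside basal clusters, 99.97 for genes at 10 CPM or more, 99.8 with at most 10% mitochondrial UMIs, 99.9 with the rule per cell, 97.45 without clusters led by other markers and 99.2 without shared barcodes. Laminin genes gave 0 and 0 of 8 (0.10, 65.8), other basement membrane genes 0 and 0 (0.03, 23.9) and the SDF1 axis 0 and 0 (0.15, 73.0). Cadherin and junction genes gave 2 and 0 of 20 (0.12, 92.3) with Cdh2 at 1.96 (1.67 to 2.30) and Ctnnd1 at 1.57 (1.5 to 1.64). Unfolded protein genes gave 0 and 0 (0.00, 11.2), leader report genes 0 and 0 (0.06, 49.5) and NF-κB genes 2 and 2 (0.07, 64.1) with Saa2 at 1.70.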

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

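Tests chosen only after the result was seen were the basal share, the barcode set and the feature list for the share of Krt14+Cdh3+ cells and all 3 tests of the genes over 4-fold apart between libraries. Krt14+Cdh3+ cells made up 0.971% of epithelial-like cells without migration and 2.28% or more in the 3 migration libraries. As the basal clusters were named, a smaller basal share does not account for this alone, since with basal and luminal cells weighted as in the no migration library the lowest of the 3 migration shares was 1.69% (1.30 to 2.20), above the upper bound of 1.21% without migration. Free RNA diluting the epithelial RNA does not either, as judged by fibroblast-like cells alone. Krt14 in those of the no migration library stood at 4.53% of its CPM in epithelial-like cells. Macrophage-like cells there had a Krt14 UMI more often than fibroblast-like cells (22.9% against 7.58% at 2000 UMIs) and were not part of this test. The feature list of the no migration library is not the cause alone, since the library labelled Ddr2-/- has the same list and a share of 2.57% (1.78 to 3.59). The barcode set of the no migration library, the only 1 with that set, and migration itself cannot be told apart, since each separates the same library from the rest, as does hypoxia. Its header is also the only 1 that names Cell Ranger 6.0.1.

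The genes between Krt14+Cdh3+ and Krt14+Cdh3− cells, led by Krt5, Tagln and Lamc2, may in large part come from basal cells being more frequent among the Krt14+Cdh3+ cells. Inside basal clusters, with cells positive at 10000 UMIs, the fold changes had a slope of 0.178 (0.147 to 0.203 over the libraries) on those over all epithelial-like cells. There edgeR called 0 genes, with 728 at an unadjusted p under 0.05, and DESeq2 called 16. Inside luminal clusters the slope was 0.805, with 0.543 without migration, 0.905 with SDF1, 0.483 with flow and 0.747 in the library labelled Ddr2-/-. The flow slope lay below the 0.5 set beforehand against this explanation, so here a mixture of cells and a program tied to Cdh3 cannot be told apart. The 2 luminal clusters with a basal marker (Trp63 or Krt5) among their top genes belong to the flow library and the library labelled Ddr2-/-. They therefore do not account for the slope with SDF1, the highest. In basal clusters thinned to 2000 UMIs per cell, 5.97%, 14.9%, 24.0% and 13.2% of cells were Krt14+Cdh3+. At 10000 UMIs these shares were 31.1%, 45.7%, 61.9% and 53.8% (order no migration, SDF1, flow, library labelled Ddr2-/-). Many basal cells were therefore called negative at the lower depth because UMIs were missed. Cdh3 UMIs still missed at 10000 UMIs stay open, as do background Krt14 UMIs without migration and a Cdh3-linked state within luminal cells. The 8 splits of the libraries are too few for a share under 0.05 (1 of 8 as large, 1563 genes for the real split and 1 for the highest other).

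For the genes between Krt14+Cdh3+ and Krt14−Cdh3− cells, the 8 splits are likewise too few for a share under 0.05, with 1 of 8 as large, 2742 genes for the real split and 0 for the highest other. Here 59.7% of the Krt14+Cdh3+ and 0.703% of the Krt14−Cdh3− cells without migration lay in basal clusters, and the basal share stays open for this comparison, since no fit was made inside basal clusters. In luminal clusters 610 genes passed at 10000 UMIs, against 3422 over all epithelial-like cells. Of 3484 epithelial genes at 50 CPM or more, 56 lay over 4-fold apart between the no migration library and both wild-type migration libraries. The feature list that the no migration library shares with the library labelled Ddr2-/- is a candidate explanation for 14 of them, such as Ptp4a1, Tonsl, Tomm6 and Fam89b, at which the latter lies nearer to it than to the migration libraries. Of those, 42.9% (17.7 to 71.1) overlap a gene that only 1 kind of feature list holds, against 1.69% (1.29 to 2.18) of the other genes, and so do 9.52% (2.66 to 22.6) of the remaining 42, so the overlap is not particular to the 14. The shared list is not the cause for all of them, since at 75.0% (61.6 to 85.6) of the 56 the library labelled Ddr2-/- lay nearer to the migration libraries. For the 42 genes nearer to the migration libraries, such as Ahcy, Cebpb and Cx3cr1, migration was not tested. It cannot be told apart from the barcode set or the software version. The 42 include mitochondrial and ribosomal genes. In the order no migration, SDF1, flow and library labelled Ddr2-/-, mt-Atp8 stood at 177.5, 6374, 4060 and 6909 CPM. In the same order mt-Nd4l stood at 343, 3284, 2707 and 3814 CPM, but mt-Nd3 at 611, 41.8, 46.0 and 75.7. Rps2 stood at 3729, 352, 302 and 385 CPM and Rpl29 at 106, 896, 612 and 949.

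A signal outside the cells used stood above the other barcodes. The 2390 barcodes of the SDF1 library all occur in the unfiltered matrix of the library labelled Ddr2-/- and carried a median of 103 UMIs there, against 1 at 551780 barcodes found in no other library. Across these barcodes the log UMIs of both libraries had a correlation of 0.838 (Spearman 0.931), against 0.00962 for the flow barcodes, and barcodes are not independent replicates. What put these UMIs there, for example molecules carried over from the SDF1 library, was not tested. Molecules carried over under their own barcodes reach few of the cells used, since 1490 of the 1501 cells of the library labelled Ddr2-/- have a barcode that no other library lists. Clustered without shared barcodes, its Krt14+Cdh3+ share was 2.43%, against 2.57% with them. Those 1490 cells held all 68 of its Ddr2 UMIs, and the 2390 SDF1 barcodes held 0 there. At a median of 103 UMIs per barcode, and with Ddr2 at 2.35 CPM over all SDF1 cells, few or none would be seen there anyway. These counts therefore do not tell where the Ddr2 UMIs came from.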

How the results depend on the processing

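Tests chosen only after the result was seen are thinning to 10000 UMIs, clusters led by markers of other classes left out, basal or luminal clusters alone, the unfiltered matrix from 1000 UMIs, and leaving out barcodes shared between libraries. The share of Krt14+Cdh3+ cells kept its lowest value without migration and its highest with flow at 1000 UMIs per cell (0.557%, 0.930%, 2.05% and 1.71%), at 10000 (5.65%, 8.59%, 15% and 10.3%) and without thinning (10.6%, 13.8%, 18.3% and 16.6%), in the order no migration, SDF1, flow and library labelled Ddr2-/-. At 2 UMIs per gene it was 0.0252%, 0.233%, 0.203% and 0.234%, where the depth limits any order and no contrast could be fitted, and without clusters led by other markers it was 3.05% with SDF1. The epithelial-like share was 69.7% with doublets kept, 95.3% from 3000 UMIs and 71.2% at resolution 1 without migration, 87.3% from 3000 UMIs and 80.8% at resolution 1 with flow, 79.0% with SDF1 and 69.2% in the library labelled Ddr2-/- without clusters led by other markers, and 81.3% in the latter from 1000 UMIs. With the rule per cell it was 78.1%, 80.4%, 72.3% and 72.6% in the order of libraries above. The no migration library was then not the lowest. The Cdh3 ratio kept its side of 1 in all 52 alternatives and moved in 14. For SDF1 against no migration it was 1.91 with the rule per cell, 2.5 without clusters led by other markers, 1.70 with TMM, 1.88 as the mean per cell, 1.53 in basal and 1.06 in luminal clusters. For flow against no migration it was 2.40 with TMM, 3.77 as the mean per cell, 2.29 in basal and 3.71 in luminal clusters, for SDF1 against flow 0.812 without clusters led by other markers, 0.499 as the mean per cell and 0.287 in luminal clusters, and for the library labelled Ddr2-/- against SDF1 2.34 in luminal clusters. The luminal values with flow and in the library labelled Ddr2-/- include 1 cluster each with a basal marker among its top genes. Genes called against Krt14−Cdh3− cells numbered 945 with thinned sums, 2653 without thinning, 3422 at 10000 UMIs, 610 in luminal clusters at 10000 UMIs, 1099 without the library as a replicate block and 1544 to 2515 with a library left out, against 2742, and no fit against them was made inside basal clusters, which hold too few such cells. Against Krt14+Cdh3− cells, with 1563 called, there were 800 at 1000 UMIs, 4070 without thinning, 412 with thinned sums, 3656 at 10000 UMIs, 942 without clusters led by other markers, 96 without the block and 1058 to 1283 with a library left out. Inside clusters at 10000 UMIs, to be set against 3656, edgeR called 691 in luminal and 0 in basal clusters (728 at an unadjusted p under 0.05), and DESeq2 16 in the latter. No paired analysis was possible between groups because each has 1 library, and the block in the contrasts is the library itself. With an estimated correlation 0 and 3 lists passed. Of 549 named gene values against Krt14+Cdh3− cells, 352 held, 184 no longer passed and 13 reversed, and of 503 against Krt14−Cdh3− cells 430 held and 73 no longer passed. Those that reversed were Il24 with the rule per cell (−0.17) and, inside basal clusters with edgeR and DESeq2, Krt5 (−0.00394 and −0.0088), Wnt10a (−0.10 and −0.18), S100a8 (0.25 and 0.36) and Ankrd1 (0.82 and 0.72), with edgeR alone Lalba (0.19), and with DESeq2 alone Lrg1 (0.27), Csn1s1 (0.68) and Tgfbi (−0.0219). Of 903 list tests 795 held, 70 no longer passed, 25 passed and 13 reversed, with adjusted p = 0.0233 for NF-κB against Krt14−Cdh3− with the rule per cell, 0.000318 and 8.07e-05 for G2/M without thinning and in luminal clusters, and against Krt14+Cdh3− 0.785 and 0.450 for interferon (10% mitochondrial UMIs, 3000 UMIs), 0.0086, 0.665, 0.688, 0.261 and 1.74e-06 for S phase (no thinning, thinned sums, without shared barcodes, basal, luminal) and 0.357, 0.601 and 0.0207 for G2/M (no thinning, basal, luminal). Of 1092 list percentiles 999 held, 80 moved and 13 reversed. Inside basal clusters these were basal genes (0.02), YAP targets (79.4) and collagens (0.11) for SDF1 against flow, the SDF1 axis (84.9) for SDF1 against no migration, and hypoxia (96.1) and collagens (98.0) for the library labelled Ddr2-/- against SDF1. Collagens also reversed as the mean per cell (23.4) and with the rule per cell (0) for SDF1 against flow, and for the library labelled Ddr2-/- at 10 CPM or more (99.97), 10% mitochondrial UMIs (99.8), the rule per cell (99.9), without clusters led by other markers (97.45) and without shared barcodes (99.2). For the results that did not hold the cause was not tested. With 33 to 77 Krt14+Cdh3+ cells per library, the simulated fits recovered 7.69% of the 1.5-fold changes against Krt14−Cdh3− cells and 32.8% against Krt14+Cdh3− cells.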

Other observations

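The class values here were picked out only after the data were seen, and no test was made on them. Cxcr4, the SDF1 receptor gene, stood highest in CPM in macrophage-like cells, at 77.4 CPM (65.6 to 90.6) without migration, 108 (86.1 to 134) with SDF1, 74.3 (58.4 to 93.1) with flow and 129 (110 to 150) in the library labelled Ddr2-/-. Endothelial-like cells stood at 65.1 (37.9 to 104) without migration, 31.2 (15.6 to 55.9) with SDF1 and 32.6 (18.7 to 53.0) in the library labelled Ddr2-/-. Luminal cells stood at 1.93, 2.75, 0.644 and 3.68 CPM, and by number held 390 of 619, 127 of 246, 16 of 118 and 110 of 306 Cxcr4 UMIs. Cxcl12, the SDF1 gene itself, stood at 919 CPM (807 to 1043) in endothelial-like cells without migration, 377 (316 to 447) with SDF1 and 269 in the library labelled Ddr2-/-. In fibroblast-like cells Cxcl12 stood at 3.19, 63.7, 11.6 and 51.4 CPM in the order of libraries given above. Lamc2 stood at 452, 378, 529 and 363 CPM in basal clusters. These classes hold 16 to 218 cells per library outside the epithelium, and the intervals cover counting error only.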
